A study of Homo sapiens with 217 samples.

How the data were processed

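All expression values come from the authors' deposited tables, one for each segment. Each gives, for a gene and a contrast, the mean normalized signal of the normal, steatosis and MASH arms, a difference, a p-value and an adjusted p-value. Expression values for single regions were not analysed here, so no model was fitted to them and no gene was tested again. The region table of the deposited files gives area, nuclei, summed signal of the counts, negative-probe signal and genes detected for 217 captured regions. Of its 26 columns 7 were read, among them a normalization factor for each region that entered no result, and 19 were not.

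The aligner, the counter and the model behind the deposited p-values are not given in the sources used here. Of the normalization they give that factor, but not the steps. The submitters' processing notes list mm10, a mouse genome, for these human samples, with no version. No coordinates are printed.

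The deposited column named as a log2 fold is a difference on the linear scale. It equals the difference of the arm means in 33.9% (unstained) to 67.7% (VWF+) of genes, to within 1e-6 of its size (or 1e-6 where that is under 1), its 3 contrasts add up without deviation, and elsewhere it departs from the arm means. It is printed as the deposited difference, in units of normalized signal, and its sign gives the direction of a called gene. Fold changes are log2 ratios of the deposited arm means, without a floor, so a ratio with an arm mean under the control probe is not resolved in size. The deposited adjusted p equals a Benjamini-Hochberg adjustment over the 3 contrasts of a table jointly. The deposited pooled mean is displaced against its genes and was not used, apart from linking condition codes to diagnoses.

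That link was made by region numbers alone. The pooled mean equals the arm means weighted by the region numbers of the codes under a single reading in VWF+, CD68+ and unstained regions, and under 2 readings in ELA2+.

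Each table has 4651 symbols. The control probe and 1 sex-linked gene were left out, and 4649 genes were tested. Against the RefSeq gene table, 4615 symbols matched a symbol, 30 a synonym and 6 neither. The symbols are printed as deposited.

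A gene was called at a deposited adjusted p under 0.05 with no fold minimum. The authors' p-values treat regions as the unit or adjust for patients in a way not given here. Regions outnumber the 10 patients in every segment, so p-values taken over regions are too small.

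The 30 gene lists and cell type markers were fixed before any value was seen, and 25 had at least 5 measured members. The median log2 ratio of a list was set against 10000 random lists of the same size, drawn from the same table and matched over 20 bins of mean expression (two-sided, Benjamini-Hochberg over the lists of a contrast). Called members were set against called genes elsewhere by Fisher's exact test. Both describe where a list lies in a table. Genes are no independent replicates. Members were also adjusted over their list alone.

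A gene's change was compared between 2 segments by a two-sided z test of the deposited differences. Standard errors were derived from the deposited p-values, the covariance was set to 0, and Benjamini-Hochberg was applied over 4649 genes. The design had foreseen log2 fold changes for this test, and the linear difference was used because it is the unit of the p-values.

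Region quantities were compared by the difference of median log10 values, with all splits enumerated where a group had fewer than 10 regions and 100000 permutations (seed 17) elsewhere. Benjamini-Hochberg was applied over the 60 tests. Zone make-up was tested by permuting the chi-square statistic, with portal regions counted in zone 1.

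Genes are named by a rule fixed before any value was seen. ICAM1 and the stain genes CD68 and ELANE are named for every contrast in the result tables, and the text gives them in most; the VWF gene was not analysed here. In MASH against normal, the 8 largest log2 ratios among called genes in each direction are named, with up to 3 members of each list that had at least 3 called members or departed from random lists. In other contrasts the numbers are 5 and 2. Between segments, the 5 genes with the smallest adjusted p per pair are named. SELE, VCAM1, PECAM1, CD68, KDM4B, HPGDS, TTC31 and TMA7 are also named or plotted where they fall outside the rule, a choice made after their values were seen. Some genes that the rule names are not reported here one by one, though every count of called genes and every list includes them.

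In a self-test, independent noise with the spread of the VWF+ log2 ratios was drawn for each gene, and shifts were added to random lists. A shift of 0.5 was found in 11 of 20 lists and a shift of 1 in 20 of 20, while 3 and 6 of 100 unchanged lists passed a p of 0.05. Changes of 3 and 6 standard errors were also added between a pair of sets of differences, simulated with the VWF+ errors. They were found in 9 and 174 of 200 genes, and 0 and 5 of 4449 unchanged genes were called. Genes and sets were drawn independently, so error rates with correlated genes or segments were not tested.

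Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.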

Results

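Liver tissue taken at surgery from 3 patients with normal liver, 3 with steatosis and 4 with metabolic dysfunction-associated steatohepatitis (MASH) was profiled by GeoMx, which counts transcript probes released by light from chosen areas of a fixed section. Sections were stained for VWF, an endothelial protein, for CD68, a protein of macrophages and monocytes, and for neutrophil elastase, called ELA2. Regions were drawn by hand in the zones of the lobule and split by their stains into VWF+, CD68+, ELA2+ and unstained segments. Not every drawn region has all 4 segments among the captured regions below. Because the stains define the segments, a stain gene that differs between segments is no finding. The region table held 217 captured regions: 40 VWF+, 43 CD68+, 51 ELA2+ and 83 unstained. Normal, steatosis and MASH arms held 8, 26 and 6 VWF+ regions, 6, 33 and 4 CD68+ regions, 15, 18 and 18 ELA2+ regions, and 17, 42 and 24 unstained regions. A region's diagnosis is labelled only as a code from 1 to 3, read here as MASH, steatosis and normal, the only reading whose region numbers match the pooled means of the deposited tables in 3 segments. In ELA2+, where MASH and steatosis have equal numbers, 2 readings match.

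Summed probe signal per region ran from 9904 to 2794850 (median 153079), nuclei from 10 to 954 (median 108) and detected genes from 964 to 4409 (median 1618). In the authors' deposited tables of arm means, the control probe, which matches no transcript, lay between 6.59 and 9.97, and the median gene between 13.5 and 15.7. Between 852 genes (ELA2+, steatosis) and 2996 genes (unstained, normal) of 4649 reached 2 times the control probe. Many genes were therefore measured close to background, and small arm means below carry that limit.

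Depth was compared first, because it stands behind every contrast of diagnoses. Area, nuclei, signal, negative-probe signal and detected genes were set between arms by two-sided permutation tests of the difference of median log10 values, and 20 of 60 tests passed an adjusted p of 0.05. ELA2+ regions differed most. Normal ELA2+ regions held a median of 344 nuclei and a signal of 943577, against 59 nuclei and 23256 in MASH (adjusted p 0.00956 and 0.00129) and 13.5 nuclei and 15153 in steatosis (0.00135 and 0.00129). This rests on the 13 normal regions of slide 2: on slide 3, 2 normal regions had a median of 10.5 nuclei and 8 MASH regions 184.5. The smallest p that 100000 permutations allow, 1e-05, was reached for nuclei of MASH against steatosis ELA2+ regions (adjusted p 0.000600). VWF+ signal was a median of 154316 in steatosis against 59657 in normal and 17966 in MASH (exact permutation tests, adjusted p 0.0280 and 0.00129). CD68+ signal was 77801 in steatosis and 21025 in MASH (exact, adjusted p 0.0408). Pooled over slides, no quantity passed in unstained regions, whose median nuclei were 371, 300 and 299.5 in normal, steatosis and MASH. On slide 3, which held all 17 normal unstained regions, median signal was 125495 in 13 MASH regions against 468161 in normal, and negative-probe signal 4.97 against 19.5 (permutation tests, both adjusted p 0.000800). These p-values are too small, since regions outnumber patients and no label ties a region to its patient.

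**Figure D1:**
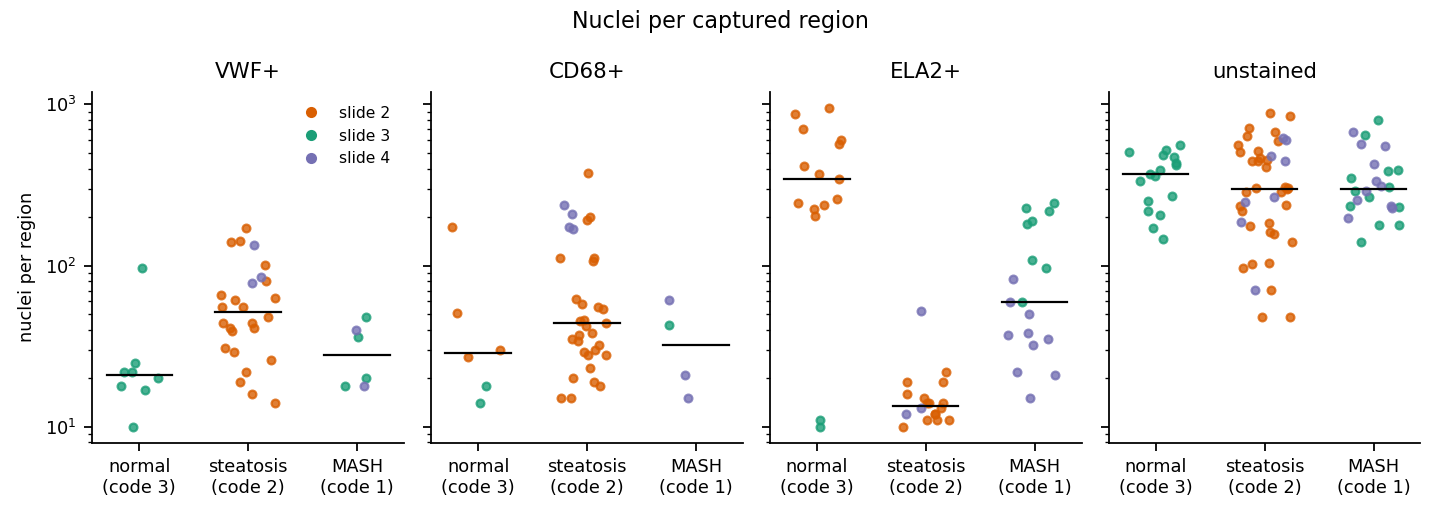
Nuclei per captured region (log axis) by segment and diagnosis, each point a region coloured by slide, with black lines at the medians. In ELA2+, the 13 normal regions of slide 2 hold 202 to 954 nuclei, while the 15 steatosis regions of that slide hold at most 22.

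Zone make-up was compared because zone-specific genes would follow it. Portal and zone 1 regions made up 5 of 8 normal, 10 of 26 steatosis and 1 of 6 MASH VWF+ regions, and no normal unstained region came from zone 3, against 18 of 42 in steatosis and 7 of 24 in MASH. No segment passed the threshold (permutation of the chi-square statistic over regions, smallest adjusted p 0.111, unstained).

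The first question was how liver endothelium differed between MASH and normal liver. VWF+ regions of MASH livers carried more transcripts of molecules by which endothelium holds leukocytes, more of the inflammatory genes under NF-kB control, and more antigen presentation genes. Sinusoidal endothelial genes were higher as well, and hepatocyte genes were far lower. In the authors' deposited table, an adjusted p of 0.05 was passed by 809 genes, 288 higher and 521 lower in MASH, and the median log2 ratio of all genes was -0.08. Of 25 fixed lists with at least 5 measured members, 16 departed from random lists of matched expression, 11 upward, and 9 did so by signed quantiles of the deposited p.

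ICAM1, the receptor for leukocyte integrins, had arm means of 8.24, 10.1 and 23.5 in normal, steatosis and MASH VWF+ regions, with a deposited difference of 18.5 between MASH and normal (adjusted p 0.000169). Its mean was 1.19 times the control probe in normal liver and 2.75 times in MASH. SELE, the endothelial selectin that slows rolling leukocytes, went from 6.81 to 18.7 (adjusted p 0.0103), VCAM1 from 11.1 to 19.5 (0.0255), and CDH5, the cadherin of endothelial junctions, from 8.63 to 18.5 (0.00326). These were the 4 members called among 9 endothelial adhesion molecules, also 4 when adjusted over the list alone. The normal mean of SELE lies under the control probe (6.94), so the size of its rise is not resolved. Normal means not far above the probe, as of ICAM1 here and of IRF1, SOCS3 and CLEC4G below, also limit the size of a rise. The control probe was itself called higher in this contrast (deposited difference 2.93, adjusted p 0.0141). The list's median log2 ratio was 0.81, above 99.98% of matched random lists (adjusted p 0.00167), while called members were not in excess by Fisher's exact test (adjusted p 0.138). VWF was not analysed here. CD68 was 18.6 in normal and 33.2 in MASH (adjusted p 0.00377), and ELANE, the elastase gene, was 11.7 and 9.45 with no call.

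Inflammatory genes rose as well. The NF-kB and TNF response list shares ICAM1 and VCAM1, both called above, with the adhesion list, and CCL2 and CXCL8 with the chemokines. Of 13 NF-kB and TNF response genes, 7 rose (10 adjusted over the list alone), with a median log2 ratio of 0.86 (adjusted p 0.000714; Fisher 0.0229). They included IRF1, an interferon-regulated transcription factor, from 7.72 to 23.6 (2.85e-08), and the monocyte attractant CCL2, from 9.83 to 33.4 (0.000484). Among 11 chemokines 3 rose (3 adjusted over the list alone; median 0.54, adjusted p 0.0136), CXCL2 and CXCL12 beside CCL2. Of 16 MHC presentation genes 7 rose, 7 adjusted over the list alone (median 0.35, adjusted p 0.00423), including B2M, the light chain of class I, from 74.6 to 203 (1.92e-08). Heat shock and immediate early genes rose in 7 of 14 (8 adjusted over the list alone; median 0.90, adjusted p 0.000714; Fisher 0.0263), among them ZFP36, whose protein destabilises cytokine mRNA, from 25 to 183 (6.28e-05). SOCS3, an inhibitor of cytokine receptors, rose from 8.07 to 42.7 (9.17e-06).

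The cell type lists moved apart. Of 13 sinusoidal endothelial genes 6 rose and none fell (7 adjusted over the list alone; median 1.05, adjusted p 0.000714), with the lectin CLEC4G from 7.2 to 23.8 (0.000204), the scavenger receptor MRC1 from 13.6 to 28.2 (0.000134) and the nuclease DNASE1L3 from 18.3 to 66.6 (0.000287). Of 15 hepatocyte genes 13 fell (15 adjusted over the list alone; median -2.40, adjusted p 0.000714; Fisher 2.76e-07), and ALB, encoding albumin, went from 6782 to 949 (7.68e-05). Acute phase and complement genes fell in 13 of 19 (median -1.82, adjusted p 0.000714), with SAA2, serum amyloid A, the only riser (100 to 169, 4.69e-05). Periportal and pericentral hepatocyte genes fell in 9 of 13 and 6 of 13 (medians -1.49 and -1.58, adjusted p 0.00423 and 0.002). Against unstained regions of the same arm, the hepatocyte list in VWF+ regions had a median log2 ratio of 0.02 in normal, -0.21 in steatosis and -2.02 in MASH liver, and the sinusoidal list -0.18, 0.11 and 0.43. VWF+ regions of normal liver therefore held as much hepatocyte transcript as unstained tissue, which limits contrasts of VWF+ regions.

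Macrophage and mesenchymal genes were higher too. The Kupffer cell list (median 0.52, adjusted p 0.0147; 3 of 11 called), the monocyte list (0.64, 0.00409; 5 of 12) and the stellate cell and fibroblast list (0.72, 0.000714; 3 of 12) all lay above random lists. They included the complement genes C1QB and C1QA and the contractile gene MYL9, which rose from 13.4 to 47.6 (0.00103). Matrix genes lay above random lists as well (median 0.68, adjusted p 0.000714), with DCN and COL4A1 higher and FN1, fibronectin, lower (99.5 to 26.6, 0.000618). Among the largest rises were ZFP36 and the haemoglobin genes HBA2, from 6.04 to 97.9 (0.00161) and HBB, from 5.55 to 48.4 (0.0464), whose normal means lie under the control probe (6.94) so that the size of their rise is not resolved, and the platelet chemokine PPBP (10.6 to 59.9, 3.91e-07). TM4SF1, a membrane protein of endothelium, went from 10.3 to 56.9 (0.00142), and NRGN and C11orf96 also rose. The largest falls were of HPGDS, a prostaglandin D synthase, from 209 to 15.2 (4.32e-08), the fibrinogen gene FGA from 722 to 65.2 (0.000708) and the cytochrome CYP2E1 from 757 to 72 (0.0461). TTC31, RBP4, SERPINA1, HRG and ALB completed the 8 largest.

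**Figure D2:**
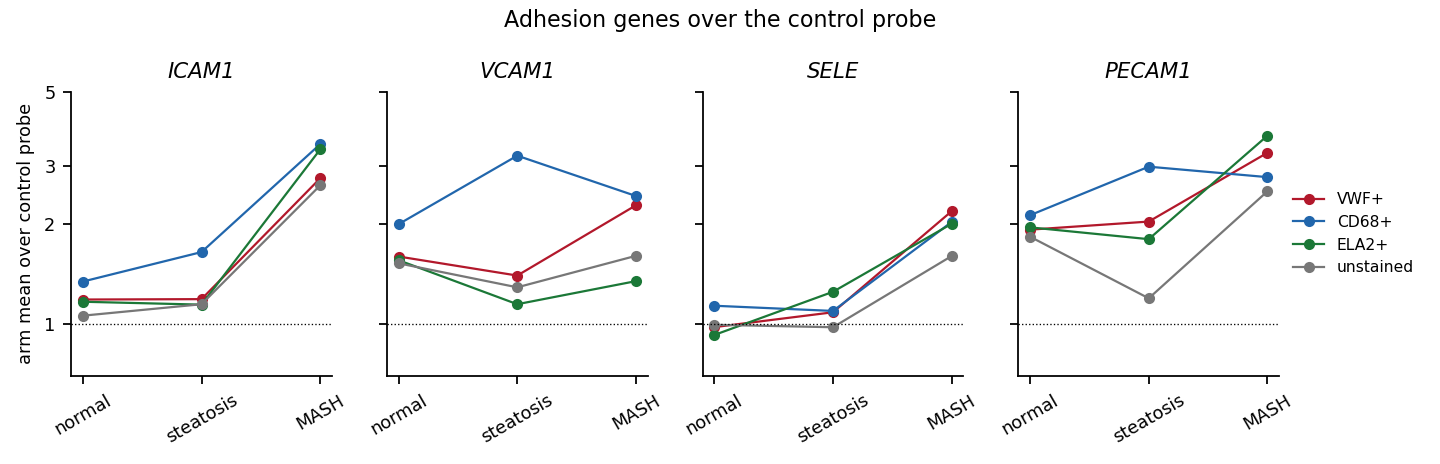
Arm means of 4 adhesion genes divided by the control probe's mean in the same arm (log axis), by diagnosis, with a line per segment and a dotted line at the control probe. ICAM1 lies between 1.06 and 1.65 in normal and steatosis in every segment and between 2.61 and 3.48 in MASH.

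The next question was whether endothelium had already changed in steatosis. For ICAM1 this was not settled: its arm means were 10.1 in steatosis and 8.24 in normal, its deposited difference was 11.5, and neither it nor SELE was called. Lists of sinusoidal, matrix and MHC genes lay above random lists by log2 ratios, though none did by signed quantiles of the deposited p. No slide held VWF+ regions of both arms, so slide and diagnosis cannot be told apart here. VWF+ regions of steatosis differed from normal in 504 genes, 218 higher and 286 lower. Only 3 of 25 lists departed from random lists, all upward: sinusoidal endothelium (median 0.56, adjusted p 0.0025; 3 of 13 called), matrix (0.54, 0.0025; 2 higher and 1 lower of 16) and MHC presentation (0.34, 0.0183; 2 of 16). CLEC1B, a lectin of sinusoidal endothelium, rose from 6.96 to 12.8 (0.0154). Its normal mean is at the control probe (6.94), which was itself called higher in this contrast (deposited difference 5.22, adjusted p 0.0111). Ribosomal protein genes fell in 9 of 18 (Fisher 0.00114) with no list shift. Among the largest rises were SUPT7L, CYP2W1, HBA2 and HBB (both from normal means under the control probe) and THRSP, a lipogenic regulator (10 to 28.1, 2.44e-05), and among the largest falls were KDM4B, NNMT, TMA7 and UTF1. CD68 was not called, and ELANE went from 11.7 to 19.3 (0.00908).

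Set against steatosis, VWF+ regions of MASH again carried more adhesion and inflammatory transcript and less hepatocyte transcript. Steatosis VWF+ regions resembled unstained tissue (r 0.985 across genes, against 0.840 in MASH), so the rise cannot be assigned to endothelium alone. Here 663 genes passed, 199 higher and 464 lower, with a median log2 ratio of -0.16 over all genes. Slide 4 alone held both arms, with 2 MASH and 3 steatosis regions, so slide and diagnosis cannot be separated for most regions. ICAM1 was not called (7.04 deposited difference, against 11.5 between steatosis and normal, neither past the threshold). SELE rose from 9.19 to 18.7 (0.0142), CDH5 from 11.5 to 18.5 (0.0131), and PECAM1, the platelet and endothelial adhesion molecule, was the other of 3 called among 9 adhesion genes (list median 0.68, adjusted p 0.00143; 3 adjusted over the list alone). CCL2 rose from 9.7 to 33.4 (2.42e-07). MHC genes rose in 7 of 16 and fell in 1 (median 0.50, adjusted p 0.000833; Fisher 0.00732). Immunoglobulin transcript was higher, with 4 of 10 B and plasma cell genes called (median 0.25, adjusted p 0.0182) and IGHG1 from 18.4 to 101 (2.96e-06). Hepatocyte genes fell in 11 of 15 (median -2.01, adjusted p 0.000833) and acute phase genes in 13 of 19 (-1.77, 0.000833), FGA, HRG, C9, HPX and RBP4 most. NAMPT, which makes NAD precursors, TM4SF1, ZFP36 and the red cell gene GYPC rose most beside IGHG1. ELANE fell from 19.3 to 9.45 (0.00266).

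The second stain asked how macrophages differ. In CD68+ regions of MASH liver, macrophage, antigen presentation and inflammatory genes were higher than in normal liver, and periportal hepatocyte genes were lower. ICAM1 was higher here too, so its rise was not a property of endothelial regions alone. CD68+ regions of MASH differed from normal in 344 genes, 97 higher and 247 lower, with a median log2 ratio of -0.17 over all genes. The MASH arm rests on 4 regions and the normal arm on 6. Only slide 3 held both arms, with 1 MASH and 2 normal regions, so slide and diagnosis cannot be separated for most regions. Against unstained regions of the same arm, the Kupffer list in CD68+ regions had a median log2 ratio of 0.36 in normal, 1.39 in steatosis and 0.85 in MASH, and the B and plasma cell list 0.59, -0.38 and 0.65, so contrasts with normal CD68+ regions do not separate captured cells from expression. ICAM1 went from 10.8 to 26.6 (0.00693). CD68 itself went from 20.4 in normal to 120 in MASH (0.0307) and ELANE did not change past the threshold. MHC genes rose in 6 of 16 (8 adjusted over the list alone; median 1.09, adjusted p 0.001; Fisher 0.02), HLA-B from 59 to 249 (5.31e-07). NF-kB genes rose in 4 of 13 (6 adjusted over the list alone; median 0.84, adjusted p 0.001), SOD2, the mitochondrial superoxide dismutase, from 20.2 to 80.8 (0.00259). The monocyte list (median 1.23, adjusted p 0.001; 3 of 12), the Kupffer list (0.62, 0.005; 2 of 11, C1QB and C1QC) and the chemokines (0.84, 0.001; 2 of 11, CXCL2 and CXCL8) lay above random lists. SGK1, a stress-induced kinase, rose most (11.6 to 92.6, 0.00941), followed by GLUL, CD68, ZFP36, the lysosomal thiol reductase IFI30, the granule proteoglycan SRGN, CHURC1 and LAPTM5. HPGDS (287 to 12.9, 1.66e-13), MAGEA4, KDM4B, IGHMBP2, TTC31, PSMG3, EBI3 and SLFNL1 fell most. Periportal genes (-1.08, 0.001; 3 of 13 fell) and acute phase genes (-0.97, 0.005; 1 of 19) lay below random lists. Portal and zone 1 regions made up 4 of 6 normal and 1 of 4 MASH CD68+ regions. Whether the fall of periportal genes follows zone or diagnosis was not tested.

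In steatosis, resident macrophage genes were higher than in normal liver in CD68+ regions, while most called genes were lower and ICAM1 was not called. The make-up of normal CD68+ regions given above limits this contrast too. The Kupffer list had a median log2 ratio of 0.93 (adjusted p 0.00125; 4 of 11 rose, 8 adjusted over the list alone), C1QB going from 40.2 to 160 (0.0142). FCGR3A, an Fc receptor, MS4A7, C1QC and GLUL were the other largest rises, and HPGDS, GRIN2A, KDM4B, C7 and SAA2 the largest falls, among 30 higher and 259 lower genes. MHC genes (0.82, 0.00125; 1 of 16 called), monocyte genes (0.41, 0.002; 2 of 12 called) and NF-kB genes (0.54, 0.00125; none called) lay above random lists, and B and plasma cell genes below (-1.34, 0.00125; 1 of 10 called). ICAM1 was 10.8 and 11.7, and CD68 20.4 and 92.6, neither called. Between steatosis and MASH, 109 genes rose and 68 fell, with a median log2 ratio of -0.13 over all genes, and ICAM1 rose from 11.7 to 26.6 (0.00151). Slide 4 alone held both of these arms, with 3 MASH and 4 steatosis regions, so slide and diagnosis cannot be separated for most regions. NF-kB genes (4 of 13 rose; median 0.62, adjusted p 0.00125), MHC genes (5 of 16; 0.33, 0.00125) and immediate early genes (4 of 14; 0.40, 0.00167) were higher, FOS going from 29.9 to 87.1 (5.99e-07). PHB, SLC22A18, CHURC1, TUB and JUNB rose most, and BHMT, CRABP2, WWP1, DTNBP1 and UBE2Z fell most.

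The third stain asked how neutrophil regions differ. In ELA2+ regions, neutrophil and monocyte genes were higher in MASH and in steatosis than in normal liver, and hepatocyte genes were lower in each. The neutrophil and monocyte lists share S100A8, S100A9 and S100A12. ICAM1 was higher in MASH alone. Normal ELA2+ regions were large and showed no neutrophil excess over unstained regions (median log2 ratio of the neutrophil list 0.02, against 1.15 in steatosis and 1.51 in MASH), so these contrasts depend on what the normal regions hold, which was not settled. MASH differed from normal in 952 genes, 154 higher and 798 lower, with a median log2 ratio of -0.22 over all genes. Only slide 3 held both arms, with 8 MASH and 2 normal regions, so slide and diagnosis cannot be separated for most regions. S100A8, a calcium-binding protein of neutrophils and monocytes, rose from 6.59 to 56.8 (0.0358), and CSF3R, the receptor for the granulocyte growth factor, from 9.3 to 38 (0.000882). These and CXCR2 were the 3 called of 7 neutrophil genes (median 1.38, adjusted p 0.000833; 4 adjusted over the list alone). The normal mean of S100A8 lies under the control probe (7.66), so the size of its rise is not resolved. The monocyte list had a median of 1.47 (0.000833; 3 of 12 rose) and the NF-kB list 1.10 (0.000833; 5 of 13 rose). ICAM1 rose from 8.96 to 25 (0.000497). ELANE was 16.1 in normal, 14.7 in steatosis and 12.2 in MASH, with no call in any contrast of ELA2+ regions, and CD68 was not called either. SRGN, NAMPT, RGS2, FCGR3A, ZFP36, LYZ and FPR1 were the other largest rises. HPGDS, KDM4B, MAGEA4, TTC31, ITIH4, FGA, ALB and FGB fell most. Hepatocyte genes fell in 13 of 15 (median -1.84, adjusted p 0.00187; Fisher 2.17e-06), acute phase genes in 14 of 19 (-1.64, 0.000833) and fatty acid oxidation genes in 7 of 15 (-0.70, 0.000833).

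In steatosis against normal, 62 genes rose and 901 fell in ELA2+ regions, with a median log2 ratio of -0.14 over all genes. S100A9 rose from 6.25 to 106 (0.000144) and S100A8 from 6.59 to 92.7 (3.89e-05), with S100A12, the neutrophil attractant CXCL8 and FPR1 also among the largest rises. S100A8 and S100A9 had normal means under the control probe (7.66), so the size of their rises is not resolved. The control probe was itself called higher in this contrast (deposited difference 2.31, adjusted p 0.0104). The neutrophil list had a median of 1.14 (0.00125; 3 of 7 rose). The 3 were S100A8, S100A9 and S100A12, which are also in the monocyte list. All 18 ribosomal protein genes fell (Fisher 1.30e-11), though random lists of like expression fell as far (median -0.89 against -0.88). HPGDS, SAA2, NNMT and GRIN2A fell most, and ICAM1 was not called (8.96 and 11.4). From steatosis to MASH, 166 genes rose and 196 fell, and ICAM1 rose from 11.4 to 25 (0.00208). Slide 4 alone held both of these arms, with 10 MASH and 3 steatosis regions, so slide and diagnosis cannot be separated for most regions. Immediate early genes rose in 7 of 14 (median 0.70, adjusted p 0.00167; Fisher 0.00104) and MHC genes in 5 of 16 (0.71, 0.00167). ZFP36, the survival factor MCL1, HLA-B and SOD2 were among the largest rises, and NEIL2, CYP3A4, PKHD1, GGH and TTC39C fell most. The neutrophil list was not shifted between MASH and steatosis.

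Unstained regions stand for parenchyma with all its unstained cells. In MASH they carried more transcript for cholesterol synthesis and uptake and for lipid storage, together with the immediate early, NF-kB and antigen presentation genes seen in stained segments. Ribosomal protein genes were lower, and the cells that carried these changes were not tested. Within slide 3 these MASH regions had less signal than normal ones, as given above, and its effect on the contrast was not tested. MASH differed from normal in 1909 genes, 590 higher and 1319 lower, with a median log2 ratio of -0.12 over all genes. All 13 measured cholesterol genes rose, also 13 adjusted over the list alone (median 0.87, adjusted p 0.001; Fisher 0.000276). HMGCS1, which starts the pathway, rose from 13.6 to 76.8 (4.18e-15), and INSIG1, its sterol sensor, from 21.4 to 94.1 (1.42e-21). Lipid storage and synthesis genes rose in 8 and fell in 2 of 15 (11 adjusted over the list alone; median 0.49, adjusted p 0.001), FASN, fatty acid synthase, from 17.2 to 60.7 (5.54e-18) and PLIN2, the lipid droplet coat, from 15.4 to 50.7 (2.87e-13). ICAM1 rose from 7.36 to 17.2 (9.73e-10), with NF-kB genes higher in 7 and lower in 2 of 13 (0.85, 0.001) and MHC genes higher in 8 of 16 (0.33, 0.001). Ribosomal protein genes fell in 15 of 18 (Fisher 0.000548) without a list shift (median -0.36, adjusted p 0.192). Acute phase genes split, 8 higher and 6 lower of 19: SAA4 rose from 30.4 to 86.8 (7.40e-21), and HAMP, the iron hormone hepcidin, fell from 37.3 to 6.59 (7.19e-08). The MASH mean of HAMP is at the control probe (6.59), so the size of its fall is not resolved. The hepatocyte list was not shifted (median -0.33, adjusted p 0.376), with 6 of 15 members lower. ZFP36, SUPT7L, CXCL2, MCL1 and JUNB were also among the largest rises, and HPGDS, KDM4B, TTC31, NPAP1L, TMA7, P4HA1 and ZNF66 the other largest falls. CD68 rose from 20.5 to 29.6 (1.82e-07) and ELANE fell from 15.8 to 12.9 (0.0371).

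In steatosis, cholesterol and lipid genes of unstained regions were higher than in normal liver, and ribosomal protein genes were lower. The cholesterol and lipid medians lay below those in MASH against normal, but a shift from steatosis to MASH is given only for cholesterol genes. All normal unstained regions were on slide 3 and no steatosis region was, so slide and diagnosis cannot be told apart in this contrast. Steatosis differed from normal in 1259 genes, 533 higher and 726 lower. Cholesterol genes (4 of 13 rose; median 0.26, adjusted p 0.0125) and lipid genes (5 rose and 1 fell of 15; 0.26, 0.00875) lay above random lists, INSIG1 going from 21.4 to 42.4 (4.37e-05). Ribosomal protein genes fell in 14 of 18 (median -0.67, adjusted p 0.0125; Fisher 0.000314), RPL7 from 213 to 104 (3.41e-20). ICAM1 arm means were 7.36 and 10.5, a gap of which the deposited difference of 10.8 (0.0006) is several times the size. SUPT7L, THRSP, GLRA1 and AKR1C2 were among the largest rises, as was HBB from a normal mean under the control probe, and KDM4B, HPGDS, P4HA1, NPAP1L and TMA7 fell most. CD68 was called higher (10.4, adjusted p 0.00905) although its arm means were 20.5 and 17.2. From steatosis to MASH, 410 genes rose and 825 fell, with a median log2 ratio of -0.11 over all genes. Slide 4 alone held both of these arms, with 11 MASH and 8 steatosis regions, so slide and diagnosis cannot be separated for most regions. Cholesterol genes rose in 8 of 13 (median 0.63, adjusted p 0.00125), FASN from 15.1 to 60.7 (1.89e-07), and ribosomal protein genes in 11 of 18 (0.33, 0.0357). ZFP36, JUNB and MCL1 were among the largest rises beside FASN, and HAMP (to a mean at the control probe), HPGDS, PZP, BHMT and C9 fell most. ICAM1 and CD68 were not called, and ELANE fell from 17.3 to 12.9 (7.33e-05).

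**Figure D3:**
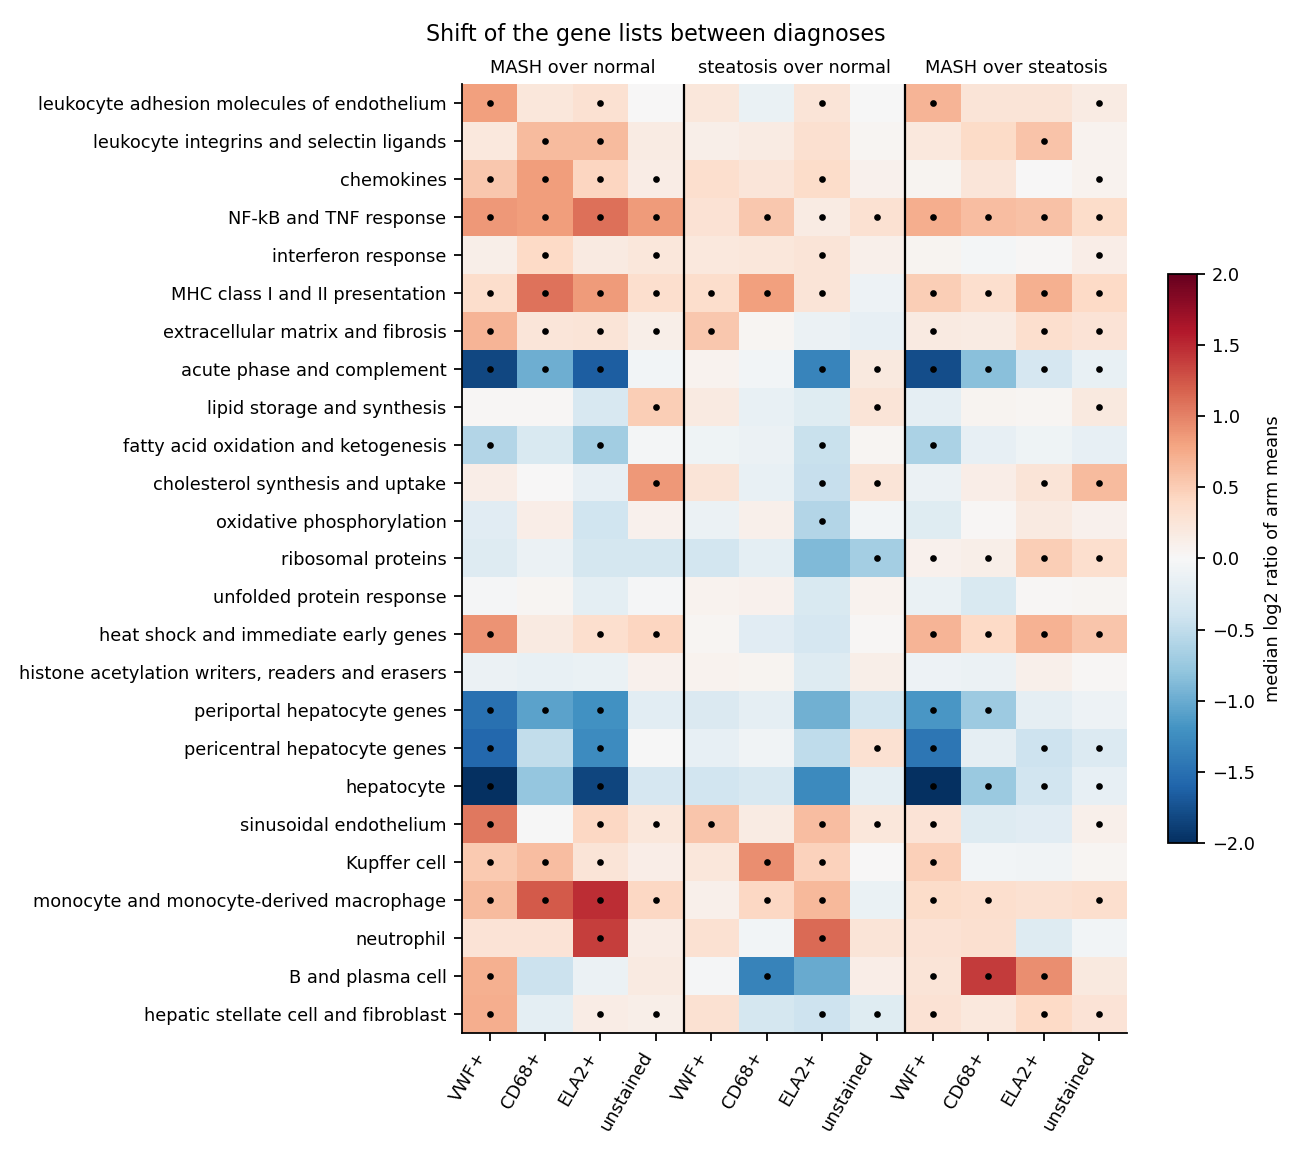
Median log2 ratio of arm means for 25 fixed gene lists, a row per list and a column per segment, for the 3 contrasts of diagnoses, with a black dot where the list departs from matched random lists at an adjusted p under 0.05. NF-kB and TNF response genes lie above random lists in MASH against normal in all 4 segments, at 0.84 to 1.10, and cholesterol genes in unstained regions alone, at 0.87.

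A last question was what MASH changed in every compartment and what it changed in one. NF-kB and MHC genes lay above random lists in all 4 segments, and cholesterol genes in unstained regions alone, though lists were not tested between segments. In MASH against normal, 26 genes were called higher in all 4 segments (0.0253 expected if the segments were independent) and 50 lower (1.348 expected). The segments were cut from the same patients, slides and fields and are not independent, so the expected numbers are too low. The 26 included ICAM1, NFKBIA, SOD2, ZFP36, SOCS3, FOS, JUNB, KLF6, MCL1, NAMPT, B2M, CD74, HLA-B, HLA-E, CDKN1A, S100A8, SRGN and C5AR1, a set listed after its values were seen. Genes called the same way in both of 2 segments numbered from 128 (VWF+ and CD68+) to 410 (VWF+ and unstained). Genes called in opposite directions numbered 14 and 51 in these pairs, and up to 89 (ELA2+ and unstained). Log2 ratios correlated across genes with Pearson's r of 0.394 to 0.622, genes being no independent replicates. The change in ICAM1 differed between no pair of segments (two-sided z test of the deposited differences, uncorrelated estimates assumed, adjusted p 0.435 to 0.995), so its rise was not shown to be larger in endothelial regions than elsewhere.

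How many other genes differed between segments depends on the unknown correlation of the estimates. The number with a different MASH change, at an adjusted p under 0.05 and with uncorrelated estimates assumed, was 187 for VWF+ and CD68+, 180 for VWF+ and ELA2+, 535 for VWF+ and unstained, 22 for CD68+ and ELA2+, 333 for CD68+ and unstained, and 646 for ELA2+ and unstained. At a correlation of 0.5 and -0.5 the first pair had 930 and 41 and CD68+ and ELA2+ 453 and 0. FASN, INSIG1, MSMO1 and SAA4 were among those that led the pair of VWF+ and unstained regions: INSIG1 had a log2 ratio of 0.34 in VWF+ and 2.14 in unstained regions, and SAA4 -0.71 and 1.51. PPBP rose in VWF+ regions (log2 ratio 2.5) against 0.13 in CD68+ and 0.36 in ELA2+ regions. SAT1, which degrades polyamines, had a log2 ratio of 0.20 in VWF+ (with a deposited difference of -9.16), 2.33 in CD68+ and 1.51 in ELA2+ regions. MXD1, a MYC antagonist, had the smallest adjusted p between ELA2+ (2.32) and CD68+ regions (0.15), log2 ratios in parentheses, but no gene of this pair passed at -0.5.

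The deposited differences did not always follow the arm means of the same table. They had the opposite sign in 124 of 1259 called genes between steatosis and normal unstained regions (9.85%), in 126 of 1235 between MASH and steatosis unstained regions (10.2%), in 32 of 504 and 13 of 663 VWF+ genes of the same contrasts, and in 5 unstained genes of MASH against normal. No called gene did so in CD68+ or ELA2+ regions, nor in VWF+ regions between MASH and normal.

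**Figure D4:**
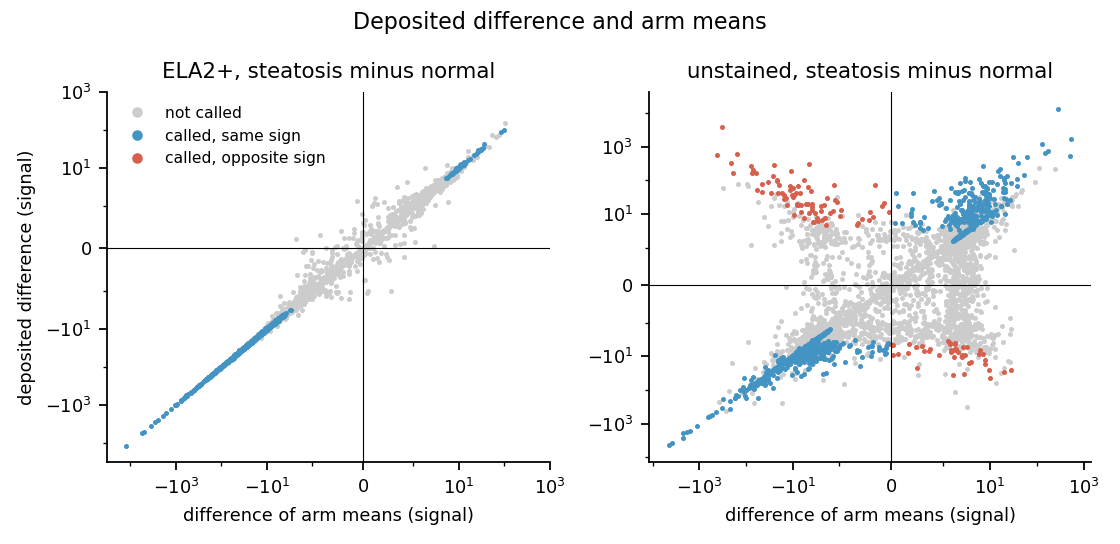
Deposited difference against the difference of the deposited arm means, a point per gene (signal units, both axes linear within 1 of zero and logarithmic beyond), for steatosis minus normal in ELA2+ (left) and unstained regions (right). Red points, called with the opposite sign, number 0 in ELA2+ and 124 in unstained regions.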

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

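All 8 tests of explanations in this part were chosen only after the result they concern was seen.

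Normal ELA2+ regions showed no excess of neutrophil genes over unstained regions. Lower depth is argued against, since their median signal was 40.6 times that of MASH ELA2+ regions (adjusted p 0.00129). Unstained tissue captured under the ELA2+ label had its needed values: 12 of the 13 normal ELA2+ regions of slide 2 lie within the 48 to 884 nuclei of that slide's 34 unstained regions, and all 13 exceed the 22 nuclei that bound its 15 other ELA2+ regions. That slide has 0 normal unstained regions, and median nuclei were 368 and 300 (permutation p 0.530). Fewer neutrophils in normal liver stays open, as only 2 normal ELA2+ regions lie outside slide 2 (median 10.5 nuclei) and S100A8 was 0.859 times the control probe in normal and 7.63 times in MASH.

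Deposited differences had a sign opposite to that of the arm means in 300 of 9466 called results. Noise around 0 in unchanged genes is argued against, since the share among called genes reached 10.2% in a contrast. Model terms that follow the slide had the value they need: the share of opposite signs over all genes fell as the arms shared more slides (Spearman's rho -0.68 over 12 contrasts, permutation p 0.0153 with 10000 draws). The 3 contrasts of a segment share arms, so that p is too small. No biological explanation was tested, and the model itself is not given in the sources used here.

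The 50 genes lower in MASH in all 4 segments include HPGDS, KDM4B, TTC31 and TMA7, 18 of them at least 2-fold lower in every segment and 4 in a fixed list. A difference between slides as the whole cause is argued against by VWF+ regions, where 4 of 6 MASH regions share the slide of all normal regions: slides alone allow a log2 ratio no lower than -0.58, and 64 genes chosen as lower in the 3 other segments had a median of -1.48 (quartiles -1.93 to -0.89). A smaller share of hepatocytes stays open, since 72 genes chosen as lower in the 3 stained segments had a median of -0.64 (-1.04 to -0.32) in unstained regions, a spread that reaches the -0.33 of the hepatocyte list. Tissue source or handling of the normal donors cannot be told apart from normal liver itself, since 3 patients carry both. Between MASH and steatosis the 50 had a median of -0.052 (-0.18 to 0.08) in unstained and -0.84 (-1.05 to -0.54) in VWF+ regions.

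With uncorrelated estimates assumed, changes between MASH and normal differed between segments in 187 genes for VWF+ and CD68+, led by H1-7 (adjusted p 2.30e-06), SAT1 (4.74e-06), HEBP1 (4.74e-06), SAA2 (8.26e-06) and PPBP (8.38e-06). For VWF+ and ELA2+ it was 180 genes, led by KCNJ9 (4.49e-05), PPBP (4.49e-05), SAT1 (8.97e-05), LMO2 (0.000228) and TMED5 (0.000265). For VWF+ and unstained regions it was 535, among the first SAA4 (4.06e-16), FASN (1.16e-15), INSIG1 (3.23e-13) and MSMO1 (9.19e-13). CD68+ and ELA2+ differed in 22, led by MXD1 (0.000738), SCCPDH (0.0102), EEF1A2 (0.0106), ARF4 (0.0106) and EIF3H (0.0106). CD68+ and unstained regions differed in 333, led by SUPT7L (3.97e-12), CNTLN (3.97e-12), ADAM15 (9.42e-12), HMGCLL1 (1.24e-11) and APMAP (1.26e-11). For SAT1 in VWF+, LMO2 in ELA2+ and SUPT7L in CD68+ regions the tested difference (-9.16, -2.77 and -191) has a sign opposite to that of the arm means (log2 ratios 0.20, 0.27 and 0.92). ELA2+ and unstained regions differed in 646, led by SAA4 (2.46e-21), FASN (6.91e-15), STYK1 (1.11e-14), MSMO1 (1.49e-12) and CD22 (3.85e-12).

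In all, 3 single regions lay far from the others of their group: a MASH CD68+ region with the highest negative-probe signal of 4 (3.96, median 1.30), a MASH VWF+ region with the most genes detected of 6 (2737, median 1225.5) and a normal VWF+ region with the most nuclei of 8 (97, median 21). Each of 4 groups of regions was tested for 5 quantities, 3 of the 40 ends were far out, and chance marks about 1 in 20 groups for a quantity.

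The control probe, which matches no transcript, was itself higher in the deposited tables for MASH against normal VWF+ regions (difference 2.93, adjusted p 0.0141), steatosis against normal VWF+ regions (5.22, 0.0111) and steatosis against normal ELA2+ regions (2.31, 0.0104). It was lower for MASH against steatosis in ELA2+ regions (-2.52, 0.00294) and unstained regions (-1.60, 0.00428).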

How the results depend on the processing

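The alternatives marked here as added (agreement in sign with the arm means, a control-probe minimum, adjustment within a contrast, signed quantiles of the deposited p, and tests within a slide) were chosen after seeing the data; the others were planned. Counts are given in the order MASH against normal, steatosis against normal, MASH against steatosis.

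Called genes kept within 1.5 times the reported number in all 12 contrasts when the lowest 25% by mean expression were left out. They also did so when the adjustment was recomputed and (added) when the arm means had to have the same sign. Those settings could not have moved a count that far. The deposited adjusted p equals the recomputed one, and at most 10.2% of the called genes of a contrast had an opposite sign. An adjusted p under 0.01, which by construction calls fewer, gave 407, 237 and 323 in VWF+, 170, 152 and 63 in CD68+, 565 (first contrast) and 137 (last) in ELA2+, and 778 (last) in unstained regions. Bonferroni gave 115, 62 and 56; 58, 58 and 15; 176, 343 and 23; and 607, 373 and 227 in VWF+, CD68+, ELA2+ and unstained regions. Requiring a 2-fold change gave 450, 62 and 243 in VWF+, 89 (second) and 78 (last) in CD68+, 428, 370 and 70 in ELA2+, and 143, 63 and 36 in unstained regions. Genes at least 2 times the control probe in an arm of the contrast (added) were adjusted again within that contrast, so filter and adjustment changed together. This gave 526 in CD68+ MASH against normal, and 139 in ELA2+ and 749 in unstained regions for MASH against steatosis. Adjustment within a contrast (added) gave 182 for ELA2+ MASH against steatosis. Where counts rose or moved under these 2 added settings the cause was not tested. Centring on the median of all genes changed the share higher by over 10 points only for unstained MASH against steatosis, from 33.2% to 43.2%.

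ICAM1 in MASH against normal kept its call under every other setting, but under Bonferroni it lost it in CD68+ (adjusted p 1) and ELA2+ (0.372). Of results for named genes, 399 kept their side of the threshold and 89 lost their call under 0.01, 218 and 270 did so under Bonferroni, and 478 and 10 with adjustment within a contrast (added). Directions by arm means (added) reversed in 8: as log2 ratios for steatosis against normal, SAA2 -0.65 and TIMP1 1.01 in VWF+, and CD68 -0.25, MS4A7 -0.13, SAA2 -0.55 and UQCRQ 0.12 in unstained regions; for MASH against steatosis, C1QA 0.51 and CALR 0.035 in unstained regions. The cause was not tested.

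The number of lists departing from random lists moved for signed quantiles (added) to 9, 0 and 10 in VWF+, 4 for CD68+ MASH against steatosis, 9 for ELA2+ steatosis against normal and 5 for unstained MASH against steatosis. It moved to 6 with unmatched random lists and to 5 with list means in VWF+ steatosis against normal, and to 14 with list means in CD68+ MASH against steatosis. Without members of another list it moved to 5 in VWF+ steatosis against normal and 7 in unstained MASH against normal. The cause was not tested. Of single lists, 124 kept and 13 lost their call with means, 125 and 12 with unmatched lists, 112 and 22 without shared members, and 84 and 52 with signed quantiles. The stellate list reversed in ELA2+ MASH against normal without shared members (0.787), and the hepatocyte list in unstained MASH against steatosis with signed quantiles (0.941).

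Genes whose change differed between segments, in the order VWF+ with CD68+, ELA2+ and unstained, CD68+ with ELA2+ and unstained, and ELA2+ with unstained, numbered 930, 792, 1067, 453, 613 and 1156 at a correlation of 0.5 between estimates, 41, 34, 244, 0, 200 and 347 at -0.5, and 73, 70, 251, 1, 202 and 347 at an adjusted p under 0.01. These counts depend on the unknown covariance of segments from the same patients. Shared genes under 0.01 numbered 60, 173, 237, 93, 76 and 219, and Spearman's rho across genes was 0.334, 0.541, 0.389, 0.454, 0.376 and 0.322.

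Of 20 region results past the threshold, 12 stayed past it on the linear scale and 15 without the plate with most regions. Few were tested within a plate or slide: all 5 tested within plate E stayed past it, as did the same 5 within slide 2 (added). These are the 5 quantities of ELA2+ steatosis against normal, with the same 13 normal regions in both settings. Within slide 4 (added) 3 of 4 lost it, with fewer regions, and signal of ELA2+ MASH against steatosis reversed (0.756). None of the 20 was tested within plates C and D or slide 3 (added), where 1 of 15, 2 of 10 and 2 of 10 other tests passed, the last 4 being signal and negative-probe signal of unstained MASH against normal regions. All 4 zone results kept their side with portal regions as a class of their own.

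No paired analysis was possible because regions are not tied to patients. Leaving out each patient or region, and other splits of the regions, were not run for the gene results, since expression values for single regions were not analysed here. Depth limits genes near background: between 18.3% (ELA2+, steatosis) and 64.4% (unstained, normal) of genes reached 2 times the control probe.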

Other observations

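No test in this part was planned, and its values were chosen after they were seen.

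Arm means of stained segments resembled those of unstained regions less in MASH than in normal liver, but the MASH segments also had a lower median signal, VWF+ and CD68+ rest on 6 and 4 MASH regions, and what the normal ELA2+ regions hold is open. Whether depth explains the difference was not tested. Across genes, which are no independent replicates, log2 arm means of VWF+ and unstained regions had a Pearson's r of 0.968 in normal, 0.985 in steatosis and 0.840 in MASH. For CD68+ regions r was 0.945, 0.922 and 0.848, and for ELA2+ regions 0.970, 0.862 and 0.868. The Kupffer list in CD68+ regions lay 0.36, 1.39 and 0.85 above unstained regions (median log2 ratio in normal, steatosis and MASH).

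Arms were unevenly spread over slides. All 8 VWF+ and 17 unstained normal regions were on slide 3, while 23 of 26 VWF+ and 34 of 42 unstained steatosis regions were on slide 2. Of 15 normal ELA2+ regions 13 were on slide 2. In every segment, MASH and steatosis regions shared only slide 4.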
